A study of Arabidopsis thaliana with 8 samples.

How the data were processed

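Transcript levels were measured on 8 arrays hybridised with total RNA of wild-type Arabidopsis thaliana, accession Columbia-0. Per the labels, 4 arrays came from plants kept at normal CO2 and 4 from plants that had spent their last 10 d at high CO2, given as 1% by volume. The titles mark the arrays at normal CO2 as 0 d, and none of these is marked 10 d. If the conditions also differed in time or age, an effect of CO2 cannot be told apart from that. The labels number the arrays 1 to 4 within each condition but do not say whether the numbers stand for separate plants, RNA extracts or hybridisations. The p-values therefore measure the spread between these arrays, which may be technical. The labels name neither the array design, the scanner nor any processing step.

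The deposited table holds 1 intensity per probe and array on a linear scale, for 3439 probes. The values run from 0 to a ceiling of 100 (rounded), which 2 to 4 probes per array reached, and 133 to 253 probes per array were listed at 0. Array means lay between 0.958 and 1.02 and array medians between 0.234 and 0.292. How the authors scaled these intensities and whether they subtracted a background is not given in the sources used here, so the values are read as relative levels. The number of arrays limits the precision of every value, and signal over background was not given.

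The medians of the positive log2 intensities differed by 0.34 between arrays, above the limit of 0.2 set before the data were examined. The arrays were therefore quantile normalized (limma 3.58.1 in R 4.3.3). Values under the 2nd percentile of positive values, an intensity of 0.0156, were raised to it before log2 was taken. The size of a fold change depends on the floor where arrays lie at it. Each probe was fitted with lmFit and eBayes with condition as the only term, and the two-sided p-values were adjusted by Benjamini-Hochberg over all probes, with a threshold of 0.05. All log2 changes are high minus normal CO2 and carry the standard error of that fit. Levels are printed as deposited intensities with their SD over 4 arrays, so their ratio can differ from the fitted fold change.

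Gene names came from a platform annotation table, updated through gene IDs to RefSeq's TAIR10.1 set, which was used for names only. Of the probes, 692 had 1 gene, 870 had several and 1877 had none listed. RefSeq matched 690 of the 692, and 1 locus had 2 probes. No gene was named from a probe with several genes.

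Before the data were examined, 22 gene lists with 400 genes were fixed, mostly of plastid pathways, with markers of other organs and housekeeping genes among them. Only 21 of these genes, in 9 lists, had a probe of their own. Lists with 5 or more measured members, of which there was 1, were tested with limma's camera (inter-gene correlation 0.01, then estimated) and fry. The mean of each list with a measured member was also tested by exact permutation over all 70 assignments of the arrays. The rule for naming genes was fixed at the same time. It took the 12 largest rises and the 12 largest falls past the threshold whose 4 values at high CO2 all lay beyond the 4 at normal CO2. It added up to 3 members per list with the smallest p among those past the threshold, and 16 fixed genes wherever measured, of which 2 were. This named 32 genes. PSBY, PSBW, PSAN, PRXIIE and CHLM, list members that did not pass the test, are given outside this rule. Other genes named outside the rule are said to be so.

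The alternatives chosen beforehand were the table without normalization, median centring, scaling on the middle of the distribution, cyclic loess, leaving out dim probes, a variance trend with robust priors, array weights, a started log, zeros as missing, the replicate number as a block, each array left out in turn, 1 value per gene, and estimated correlation or ranks for the list test. After the data were seen, a position correction was added. The log2 change depended on the probe number in a cycle, and a scan of periods from 50 to 900 put it at 288 numbers. Probes were put into 24 classes, each 12 numbers wide within the cycle, and the median deviation of a class from the probe means was subtracted per array. The position of a probe means its place in this cycle of numbers. The sources used here do not say whether the numbers follow the layout of the array. Fits that treated arrays 1 and 2, and arrays 3 and 4, of a condition as related were also added then.

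The procedure was tested on simulated data for high against normal CO2 with all 3439 probes, of which 200 were changed. With independent arrays, 49% of the 2-fold and 87% of the 4-fold changes were recovered and 6.21% of the calls were false. False calls made up 16.0% when arrays were correlated in pairs as measured, and 9.79% with the pairs as a random block. They made up 37.9% with a simulated position profile and 5.56% after the position correction. In the measured data the correction left part of the dependence on probe number, so the simulated profile does not show how well it works there. The simulation changed 200 probes, while 1329 were called in the measured data. These shares of false calls therefore describe the simulations and cannot be carried over to the measured data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probes were neither filtered by brightness nor left out in the fit reported.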

Results

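The data comprised 8 arrays of wild-type Arabidopsis plants, 4 at normal CO2 and 4 after 10 d at 1% CO2, with 3439 probes each. The comparison asked which transcripts differed after 10 d at high CO2.

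After 10 d at high CO2, the 12 largest rises among probes with 1 gene ran from 2.50 to 4.65 on the log2 scale and the 12 largest falls from -1.85 to -3.30. APTX (AT5G01310), an aprataxin-like protein, was among the rises. Its intensity went from 0.0282 ± 0.0309 to 0.702 ± 0.161 (SD, n = 4 per condition), a 25.1-fold change (log2 4.65 ± 0.49 SE, limma adjusted p = 0.000483). AT3G56810 went from 0.555 ± 0.197 to 10.0 ± 0.343, which was 19.5-fold (log2 4.28 ± 0.24, adjusted p = 5.3e-05). AT5G58330, the plastid NADP-dependent malate dehydrogenase that reduces oxaloacetate to malate, rose 5.85-fold from 0.462 ± 0.118 to 2.71 ± 0.231 (log2 2.55 ± 0.20, adjusted p = 0.000142). AT4G31210, a type IA DNA topoisomerase family gene, fell from 0.425 ± 0.148 to 0.0451 ± 0.0492, with a log2 change of -3.30 ± 0.65 (adjusted p = 0.00685).

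Among the other genes with large rises, AT3G25680, AT2G31800 and AT1G27610 rose by 4.30, 4.30 and 4.26 on the log2 scale. Each of them lay at the floor of the scale in 2 or 3 of the 4 arrays at normal CO2, as APTX did in 2, so these folds and their order depend on the floor. With a started log in its place, APTX, AT3G25680, AT2G31800 and AT1G27610 stood at 3.71, 3.13, 3.01 and 3.04, and AT3G56810, at 4.19, was highest of the 12. With zeros as missing they stood at 5.34, 5.04, 4.71 and 5.44, and AT1G27610 was highest. AT4G35660 rose 8.47-fold, from 1.13 ± 0.319 to 9.58 ± 2.43, well above the floor on every array. AT3G60590 rose by 3.09 on the log2 scale (2.25 with the started log), AT2G30100 by 2.72 and AT5G46560 by 2.69, or by 2.08 after the correction for probe position. AT5G44000, of the glutathione S-transferase family, rose by 2.53 (1.87 with the started log). AT5G19050, at the floor in 2 of the 4 arrays at normal CO2, rose by 2.50 ± 0.64 (adjusted p = 0.0195), or 1.62 with the started log. This call ended without array 4 of high CO2 (2.21, adjusted p = 0.05002).

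AT2G46630 fell from 2.76 ± 0.341 to 0.652 ± 0.186, a log2 change of -2.17 ± 0.18 (adjusted p = 0.000151). AT2G32040, of the folate and biopterin transporter family, fell from 0.510 ± 0.0930 to 0.116 ± 0.0281 (log2 -2.05 ± 0.24, adjusted p = 0.000779). AT5G40050 fell from 0.371 ± 0.0521 to 0.0988 ± 0.0286 (log2 -1.85 ± 0.19). AT1G25500, a choline transporter-like gene, was listed at 0 in 3 of the 4 arrays at high CO2 and at 0.000855 in the other. It fell (adjusted p = 0.000271), but the floor sets the size of its log2 change and SE (-2.57, and -1.73 with the started log). AT5G44150, AT2G28200 (a C2H2 zinc finger gene) and AT1G08845 (ribosomal L18p/L5e family) fell with log2 changes of -2.46, -2.34 and -2.08, and AT5G44150 and AT1G08845 lay at the floor in 2 of the 4 arrays at high CO2. With the started log these 3 stood at -1.81, -1.65 and -1.43, and AT4G31210, at the floor in 1 array at high CO2, at -2.53. AT4G37230, AT5G19210 and iqd32 (AT1G19870), an IQ-domain gene, fell with log2 changes of -2.52, -1.85 and -1.88 and adjusted p of 0.0245, 0.0213 and 0.0415. Leaving out any array of normal CO2 ended the calls of AT4G37230 and iqd32, as did array 1 of high CO2 for AT4G37230, with log2 changes of about the same size (-2.57 to -2.46, adjusted p from 0.0556 to 0.0582 for AT4G37230, and -1.95 to -1.83, adjusted p from 0.0846 to 0.0997 for iqd32). Leaving out array 2, 3 or 4 of normal CO2 ended that of AT5G19210 (log2 -1.86 to -1.77, adjusted p from 0.0509 to 0.0584). Without array 3 of high CO2, or with zeros as missing, the log2 change of AT4G37230 was -1.83 (adjusted p = 0.00950 without the array), and without array 4 of high CO2 that of iqd32 was -1.21 (adjusted p = 0.000591).

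**Figure D1:**
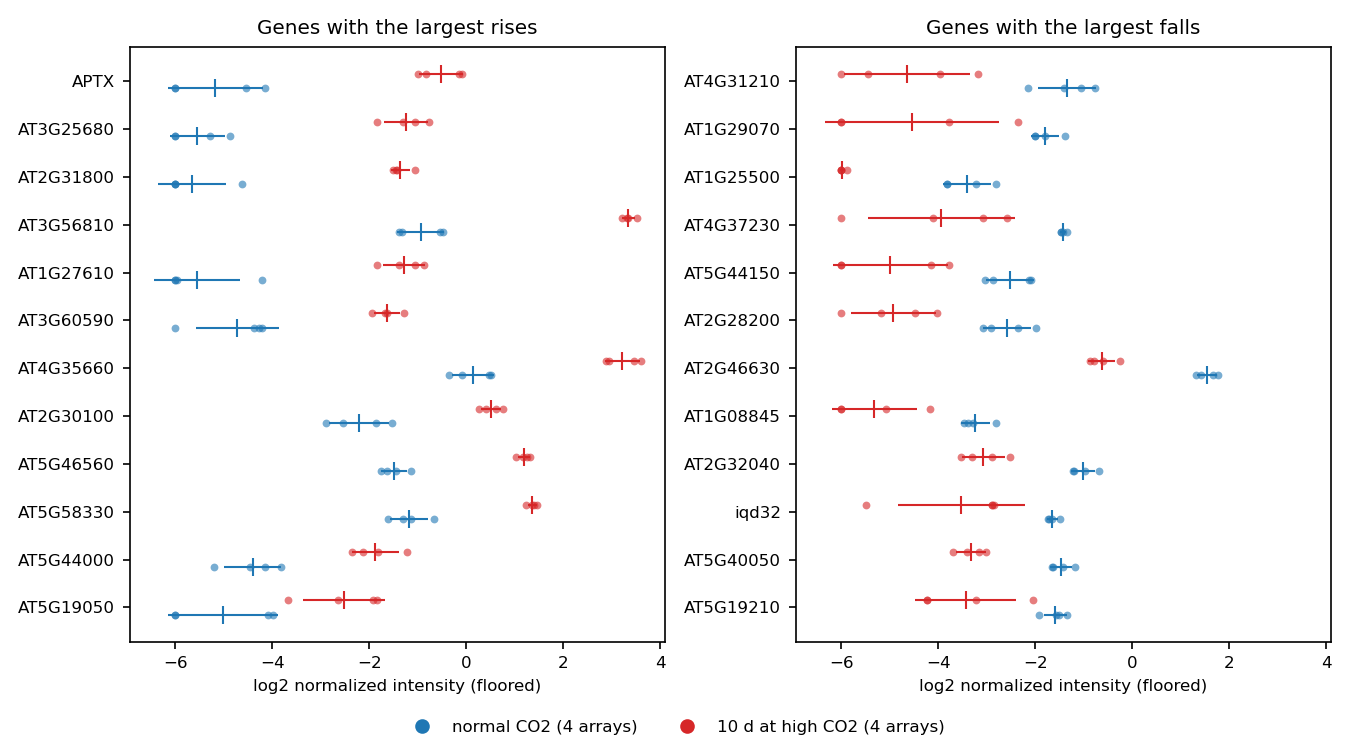
Log2 normalized intensity (x axis, with values under the floor raised to it) of the 12 genes with the largest rises (left) and the 12 with the largest falls (right). Points are single arrays, ticks are means and lines are ± SD over 4 arrays, blue for normal and red for high CO2. For all 24 genes the points of the conditions do not overlap, because the naming rule required it, and several genes have points at the floor in 1 condition.

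Of all 3439 probes 38.6% were called, so a few calls in a list do not by themselves set it apart. Of the photosystem II list, 4 members were measured, of which 1 rose, 1 fell and 2 did not pass the test, over all probes and adjusted over the list alone. LHB1B2 (AT2G34420), a chlorophyll-binding antenna protein of photosystem II, rose from 2.21 ± 0.249 to 6.32 ± 0.820 (log2 1.37 ± 0.16, adjusted p = 0.000629). Its near-identical paralogs may bind the same probe, so the value can stand for several genes. PSB27 (AT1G03600), a photosystem II assembly factor, fell from 4.32 ± 0.408 to 2.76 ± 0.207 (log2 -0.77 ± 0.11, adjusted p = 0.00166). PSBY and PSBW, subunits of photosystem II, had log2 changes of 0.22 ± 0.16 and 0.41 ± 0.31 (adjusted p = 0.288 and 0.336). The only measured member of the photosystem I list, PSAN, had a log2 change of -0.17 ± 0.12 (adjusted p = 0.307).

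Carbon metabolism was covered by few probes. Of the Calvin-Benson cycle list, 2 members were measured and 1 fell. SBPASE (AT3G55800), sedoheptulose-bisphosphatase, fell from 0.837 ± 0.0955 to 0.574 ± 0.136 (log2 -0.52 ± 0.15, adjusted p = 0.0324). That call was not past the threshold after correction for the position of probes (log2 -0.28, adjusted p = 0.212), or without array 1, 2 or 4 of normal CO2 or array 2 or 3 of high CO2 (log2 -0.54 to -0.48, adjusted p from 0.0531 to 0.0783). PRK (AT1G32060), phosphoribulokinase, had a log2 change of 0.065 ± 0.16 (adjusted p = 0.770), and its sign turned to -0.037 without array 1 of normal CO2 and to -0.0064 without array 2 of high CO2. AT5G17630, the xylulose 5-phosphate translocator of the plastid envelope and the only measured member of the list of starch breakdown and sugar export, rose from 0.740 ± 0.0999 to 1.71 ± 0.304 (log2 1.17 ± 0.14, adjusted p = 0.000814). PLGG1 (AT1G32080), the plastid glycolate and glycerate transporter and the only measured gene of photorespiration, had a log2 change of -0.75 ± 0.27 (adjusted p = 0.0605). Its list held 1 measured gene, so adjustment over the list alone left the limma p at its unadjusted 0.0249. That adds no support beyond the test over all probes. PLGG1 was named after its values were seen.

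Of the 6 measured plastid ribosomal proteins, 2 fell and 0 rose, and none passed when adjusted over the list alone. AT1G29070, the large-subunit protein PRPL34, fell from 0.297 ± 0.0710 to 0.0686 ± 0.100 (log2 -2.74 ± 0.82, adjusted p = 0.0346). AT1G64510, the small-subunit protein PRPS6, fell from 0.285 ± 0.0169 to 0.0983 ± 0.0603 (log2 -1.81 ± 0.60, adjusted p = 0.0475). With the started log the log2 change of AT1G29070, at the floor in 2 arrays at high CO2, was -2.10. Both calls ended without any array of normal CO2 or without array 4 of high CO2, and also without array 2 (AT1G29070) or array 3 (AT1G64510) of high CO2. The log2 change then ran from -2.88 to -2.23 and the adjusted p from 0.0692 to 0.0809 for AT1G29070, and from -2.02 to -1.80 and from 0.0513 to 0.105 for AT1G64510. Without array 2 of high CO2 the log2 change of AT1G64510 was -1.15 (adjusted p = 0.00233), and without array 3 of high CO2 that of AT1G29070 was -3.44 (adjusted p = 0.00610). The list as a whole was not shifted against the other probes (mean log2 -0.65, median -0.067, camera p = 0.684, and p = 0.691 with an estimated correlation), and fry gave p = 0.521 for a shift one way and 0.188 for change in either direction. The mean of the list against its own spread over arrays gave an exact two-sided permutation p = 0.0286, the smallest that 70 assignments of the arrays can give, which does not compare it with other probes either. The permutation takes the arrays as independent. Only 3 splits keep arrays 1 and 2, and arrays 3 and 4, of a condition together, too few for a p under 0.05. Over the 9 lists with a measured member, 4 lists had the permutation p of 0.0286 (plastid ribosomal proteins, plastid redox proteins, fatty acid synthesis, and starch breakdown and sugar export), and it was 0.0643 after Benjamini-Hochberg adjustment of the exact tests. For the list of starch breakdown and sugar export, with 1 measured gene, that p only says that the conditions did not overlap. The same held for 39.6% of all probes. No list but the plastid ribosomal proteins had enough members with probes of 1 gene to test, so 0 lists rose and 0 fell in camera, at an unadjusted p under 0.05 as well.

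Of 3 measured plastid redox proteins 2 fell and 0 rose, over all probes and adjusted over the list alone, where 38.6% of all probes were called. AT2G04700, the catalytic subunit of ferredoxin-thioredoxin reductase, fell from 1.23 ± 0.0426 to 0.711 ± 0.0668 (log2 -0.78 ± 0.14, adjusted p = 0.00520). NTRC (AT2G41680), the plastid NADPH-dependent thioredoxin reductase, fell from 0.296 ± 0.0496 to 0.181 ± 0.0248 (log2 -0.65 ± 0.20, adjusted p = 0.0387). The NTRC call ended after the position correction (log2 -0.16, adjusted p = 0.576), and without array 1, 3 or 4 of normal CO2 or array 2, 3 or 4 of high CO2 (log2 -0.70 to -0.50, adjusted p from 0.0502 to 0.0963). PRXIIE (AT3G52960), a plastid peroxiredoxin, had a log2 change of -0.15 ± 0.21 (adjusted p = 0.597). Both measured genes of fatty acid synthesis passed, as rises, when adjusted over their list of 2 alone (limma adjusted p = 0.0407 for each). That is little more than an unadjusted test, and 1650 probes had an unadjusted p under 0.05. Adjusted over all probes 0 passed. Both genes were named after their values were seen. FATB (AT1G08510), an acyl carrier protein thioesterase, had a log2 change of 1.31 ± 0.53 (adjusted p = 0.0887 over all probes), and AT1G24360, a ketoacyl reductase, of 0.92 ± 0.35 (adjusted p = 0.0763). CHLM (AT4G25080), a methyltransferase of chlorophyll synthesis and the only measured gene of its list, had a log2 change of -0.72 ± 0.32 (adjusted p = 0.119).

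**Figure D2:**
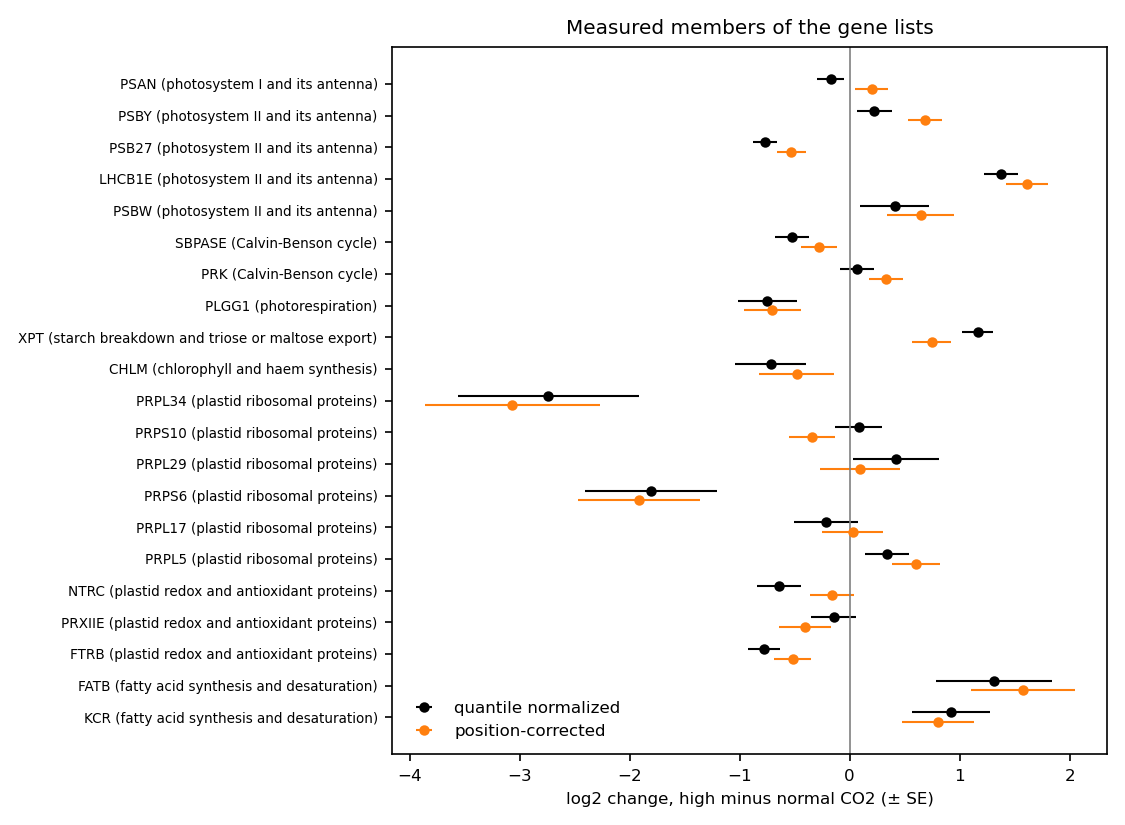
Log2 change, high minus normal CO2 (x axis), of the 21 measured members of the gene lists, as points with ± SE, in black after quantile normalization and in orange after the position correction as well. LHCB1E is LHB1B2. It stood at 1.37 and 1.61, while NTRC moved from -0.65 to -0.16 with the correction.

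Over all probes, 662 rose and 667 fell, together 38.6% of the 3439, and the median log2 change was -0.025. Rises made up 49.8% of the calls, a share that depends on the scaling of the arrays, since it was 46.2% in the table without normalization and 54.1% with scaling on the middle of the distribution. Changes of at least 1.5-fold were found for 605 rising and 600 falling probes, and of at least 2-fold for 432 and 364. Among the 692 probes with 1 gene, 144 rose and 126 fell. The 4 values of a condition all lay beyond the 4 of the other for 1363 probes, or 39.6%, where chance gives 2.86% only if the 8 arrays are independent, and arrays of a condition resembled each other in pairs. Arrays of different conditions correlated across probes at r of 0.801 to 0.846, and arrays of 1 condition at 0.883 to 0.975, where probes are not independent replicates.

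The log2 change depended on the probe number. In a cycle of 288 numbers, the mean log2 change of classes of 12 numbers went from -0.67 ± 0.066 (SE), in a class where 9 probes rose and 73 fell, to 0.66 ± 0.077, where 54 rose and 7 fell. After correction for this, 614 probes rose and 514 fell, and 878 of these calls were among the 1329 made without it, all in the same direction. The correction did not remove all of the dependence. Log2 changes of probes 6 and 12 numbers apart still correlated at 0.108 and 0.106, against 0.237 and 0.210 before. In 1000 shuffles of the uncorrected changes the largest correlation was 0.0799. At 282 and 294 numbers apart the corrected changes correlated at 0.102 and 0.091, above that value, so part of the cycle remained. At 1 and 288 numbers apart they correlated at 0.044 and 0.058, under it, which does not show that no dependence was left. Of the 21 measured list members, 4 rose and 4 fell after the correction, against 2 and 6 without it, with PSBY (log2 0.68, adjusted p = 0.0120) and FATB (log2 1.57, adjusted p = 0.0350) then among the rises. All 12 of the largest rises and all 12 of the largest falls among named genes were still past the threshold after the correction. Arrays 1 and 2, and arrays 3 and 4, of a condition resembled each other. With each pair averaged, 2 against 2, limma called 0 probes (lowest adjusted p = 0.0515, with 1217 probes at an unadjusted p under 0.05), against 514 rises and 513 falls with the pairs as a random block. The random block ended the calls of AT5G19050, AT4G37230, AT5G19210, iqd32, AT1G29070, AT1G64510, SBPASE and NTRC (adjusted p from 0.0564 to 0.121). Their log2 changes stayed as in the fit without it, since the block changes only the error. With the position correction and the random block together, 25 of the 31 named calls were past the threshold. AT2G04700 (adjusted p = 0.0775) was not, nor were AT1G29070, AT4G37230, AT1G64510, SBPASE and NTRC (adjusted p from 0.0641 to 0.670).

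**Figure D3:**
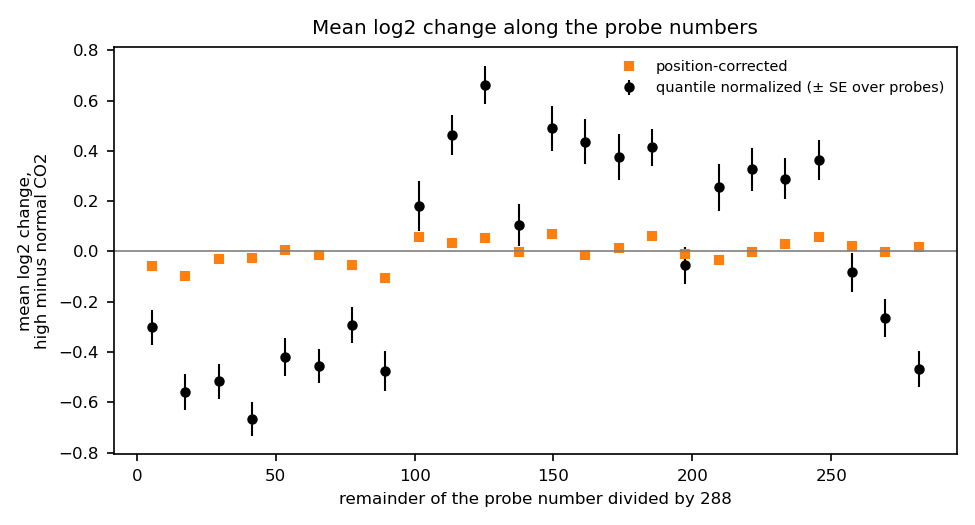
Mean log2 change, high minus normal CO2 (y axis), of probes in 24 classes by the remainder of their probe number divided by 288 (x axis). Black points are means with ± SE over the probes of a class after quantile normalization, from -0.67 to 0.66. Orange squares are the means after the position correction, which lay between -0.11 and 0.068. Their flatness follows from the correction itself, which subtracts class medians.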

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

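Of the tests in this part, those on the position-dependent signal, on a background gradient, on scaling and on the resemblance of array pairs were chosen after the result was seen.

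In 5 of 70 groups of 4 arrays, 1 array stood apart from the other 3 by more than Dixon's limit. Chance gives about 3.5 for values that are not tied. For genes the ratios were taken on log2 values after the floor, which ties low values. The count of 5 therefore cannot be set against 3.5. For AT2G31800 at normal CO2 the gap took all of the range (ratio 1), array 1 being highest at an intensity of 0.0545 against 0.0158 to 0.0212, which the floor merged. For AT1G27610 at normal CO2 the ratio was 0.972, with array 1 highest at 0.0688 against 0.00246 to 0.0268. The floor raised 2 of the others, the lowest among them, so it shapes this ratio. For AT3G60590 at normal CO2 it was 0.909, with array 4 lowest at 0.0203 against 0.0556 to 0.0661. For AT1G25500 at high CO2 it was 1, with array 4 at 0.000855 and the others at 0, which the floor merged. For iqd32 at high CO2 it was 0.984, with array 4 lowest at 0.00606 against 0.118 to 0.148.

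Chance division of the arrays can be excluded as the source of the number of changed probes only if the 8 arrays are taken as independent. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, called as many as 1329 probes, and the highest of the others called 1. With the position correction the real split called 1128 probes, again 1 of 35 splits reached that, and the highest other called 1. Splits that keep arrays 1 and 2, and arrays 3 and 4, of a condition together number 3, too few for a share under 0.05, and the highest of the others called 1.

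The dependence of the log2 change on probe number in a repeating cycle was weighed against 3 explanations. Position classes took 15.5% of the variance of the log2 change and 10.4% of that between arrays 1 and 2 and arrays 3 and 4 of normal CO2, where 10000 shuffles reached at most 1.76%. The same difference at high CO2 gave 2.21% against at most 1.70%, and within pairs position took 0.762% and 0.481% at normal CO2, under the highest shuffles (1.63% and 1.59%), and 1.01% and 1.67% at high CO2, where the highest were 1.64% and 1.60%, so a position-dependent signal on the arrays stays open. A minority of truly responding genes gathered in some classes would move 1 quartile of a class, but the 25th and 75th percentiles moved together with a correlation of 0.956 over the 24 classes, at least 0.950 whichever class was left out. A background that adds to every spot would fade in bright probes, but the class means spread 0.895 times as widely in the brightest of 5 equal bins of probes as in the dimmest. A response to CO2 shared by most genes of a class was not tested.

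The resemblance of arrays 1 and 2, and of arrays 3 and 4, within a condition was also weighed. At normal CO2 the arrays of a pair correlated at 0.965 and 0.975 and arrays of different pairs at 0.941 to 0.949. At high CO2 the values were 0.925 and 0.898 against 0.883 to 0.894. The position correction removed on average 9.32% of the excess variance between pairs and quantile normalization 12.4%, which argues against either as the main source. Shared plants, extracts or hybridisations within a pair stay open, since the labels do not describe them, and no biological explanation was tested.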

How the results depend on the processing

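The position corrections, the fits with pairs of arrays, the subsets of replicates and the counting of probes of several genes in lists were chosen after seeing the data. Rises numbered 662 and falls 667, and each stayed within 1.5 times of that except as given here. Without the dimmest 50% of probes, so with fewer probes tested, 440 rose and 423 changed at least 2-fold. Replicates 1 and 2 alone gave 320 rises, 339 falls, 652 changes of at least 1.5-fold and 485 of at least 2-fold, and replicates 3 and 4 alone gave 420 falls, with fewer arrays. Averaging arrays in pairs, which leaves 2 against 2, gave 0 rises, 0 falls and 0 changes at either fold. With position correction and pairs as a random block, 360 fell, and 715 of the 836 calls were among those made without either. Rises made up 49.8% of calls, 46.2% in the table as deposited, 54.1% scaled on the middle of the distribution, 51.8% with cyclic loess, 45.5% without the dimmest 50% of probes, 46.3% with array weights, 50.8% with zeros as missing, 54.4% position-corrected, 54.0% with narrow classes, 50.05% with pairs as a random block, 52.6% in replicates 3 and 4, and 56.9% with position correction and random block. It ran from 47.7% to 52.5% leaving out 1 array at a time. The cause was not tested. The median log2 change ran from -0.11 to -0.00361 over all 27 alternatives, and 0 lists rose or fell in camera in each that could test one. PRK, which did not pass the test, ran from -0.037 to 0.14 leaving out 1 array and stood at -0.28 in replicates 3 and 4, 0.40 in replicates 1 and 2, 0.33 position-corrected and 0.42 with narrow classes.

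Of the 31 named genes past the threshold, 0 changed direction in any alternative, 26 stayed past it in each alternative chosen beforehand that kept all 8 arrays and tested them, and 23 did so without each array in turn. The 5 that did not stay past it with all arrays were iqd32, SBPASE, AT1G64510, AT1G29070 and NTRC. For all 31 the values of the conditions did not overlap, which the naming rule required for most of them. That choice nearly shut out a change of direction, also when arrays are left out. After the position correction 29 of the 31 were past the threshold, and 23 with the pairs as a random block. With narrow classes AT5G46560 stood at 1.83 and AT5G19210 at -2.46. The same replicate numbers in both conditions did not pair the arrays. Deviations of same-numbered arrays correlated at 0.060, -0.0054, 0.016 and 0.091, and 2 of the 4 arrays at normal CO2 correlated best with their own number. The replicate block gave 576 rises and 562 falls, with rises at 50.6% of calls. The share of probes called rose with brightness over 5 equal bins, from 19.0% in the dimmest over 30.2%, 38.7% and 47.2% to 58.0% in the brightest. The median SD over arrays at high CO2 fell from 0.897 in the dimmest to 0.190 in the brightest bin (log2). At normal CO2 it fell from 0.466 to 0.167. Dim probes thus varied more at high CO2, while the fit took a common variance for both conditions. Whether the floor plays a part was not tested.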

Other observations

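Genes outside the naming rule were looked up by keyword after their values were seen. Of 5 genes of the plastid NAD(P)H dehydrogenase complex and its assembly, 1 rose and 1 fell. CRR41 (AT1G51100) rose from 0.348 ± 0.0665 to 0.543 ± 0.143 (SD, n = 4; log2 0.68 ± 0.19 SE, limma adjusted p = 0.0262), and PIFI (AT3G15840) fell from 0.109 ± 0.0292 to 0.0344 ± 0.0359 (log2 -1.55 ± 0.49, adjusted p = 0.0412). NdhN, NdhS and CRR21 had log2 changes of -0.50, 0.56 and 0.11 and did not pass the test, although NdhN did so after the position correction (log2 -0.79, adjusted p = 0.0302). The group as a whole was not shifted (camera p = 0.942, and p = 0.956 with an estimated correlation). LPA19 (AT1G05385), a photosystem II assembly factor, fell from 1.15 ± 0.0204 to 0.508 ± 0.113 (log2 -1.15 ± 0.13, adjusted p = 0.000662), and after the position correction its log2 change was -0.51 ± 0.18 (adjusted p = 0.0608).

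Of 4 cellulase-family genes (GH9B), GH9B11 (AT2G44560) fell from 0.400 ± 0.0705 to 0.141 ± 0.0827 (log2 -1.58 ± 0.43, adjusted p = 0.0246) and the other 3 did not pass the test. The mean log2 change of these 4 was -1.06 (exact permutation p = 0.0286, the smallest that 70 assignments can give, and 0.114 adjusted over 4 keyword groups). That p takes the arrays as independent and comes from a group chosen after its values were seen, so it gives no support. With the position correction GH9B11 stood at -1.15 ± 0.41 (adjusted p = 0.0617), and 0 of these 4 genes were past the threshold. GH9B8 went the other way, with a log2 change of 0.22, or 0.68 with the correction. Of 4 calmodulin-like and IQ-domain genes 1 rose and 1, iqd32, fell (mean log2 -0.31). CML41 (AT3G50770), a calmodulin-like protein, rose from 0.153 ± 0.0669 to 0.304 ± 0.0234 (log2 1.13 ± 0.28, adjusted p = 0.0172). Among the brightest spots, the unnamed probe 1431 was at the ceiling on all 4 arrays at high CO2 and at 51.3 ± 17.3 at normal CO2 (adjusted p = 0.0145), so the size of its rise was not measured. The unnamed probe 812 was at the ceiling on all 4 arrays at normal CO2 and at 52.4 ± 10.4 at high CO2 (adjusted p = 0.00175), so the size of its fall was not measured.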
